A study of Mus musculus with 10 samples.

How the data were processed

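Gene expression was measured by RNA sequencing in splenic B cells of mice. The fibrosis group (5 libraries) came from mice with liver fibrosis after 4 weeks of intraperitoneal carbon tetrachloride, a solvent that injures hepatocytes and is widely used to induce liver fibrosis. The control group (5 libraries) came from wildtype mice. Libraries were grouped by the disease state in the labels. Replicates are numbered 1 to 5 in both groups, and nothing in the labels ties a number to a shared animal, day or batch. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be partly technical. How the B cells were isolated is not given in the sources used here.

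Per the labels' protocols, mRNA was purified from total RNA with poly-T beads, fragmented, reverse transcribed with random hexamers and amplified by PCR. The submitters' processing notes name the genome build GRCm38, also called mm10. The aligner, the counting program and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical family members cannot be told apart. The authors deposited a table of whole-number read counts per gene, not normalised, with one column per library and each gene's symbol, coordinates, exon length and biotype. They also deposited FPKM, which divides counts by gene length and library size. From the values, each FPKM equals the deposited count divided by the listed length and the library total, times a factor per library between 0.935 and 1.07 that is the same for all genes; how the authors made that factor is not given in the sources used here.

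The counts were the input of the main test, and all columns of sample values were used. Total counts ranged from 13439100 to 17954551 per library. Of the 54532 genes in the table, 20984 had no count in any library. edgeR 4.0.16 (R 4.3.3) kept 14283 genes with filterByExpr at its defaults, and these held 99.9% of the counts. Libraries were scaled by TMM, and groups were compared by edgeR's quasi-likelihood test with robust dispersion and no covariate, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes are log2, fibrosis minus control, with the standard error taken as the absolute log2 fold change divided by the square root of the test's F. Levels are counts scaled by TMM library size (CPM), given as mean ± SD. The biological coefficient of variation was 0.183. The median standard error was 0.37 for genes under 1 CPM, 0.25 from 1 to 10 CPM, 0.12 from 10 to 100 CPM and 0.11 above.

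Fixed before the data were examined were 45 gene lists with 902 symbols, covering B cell states, inflammatory and stress responses, metabolism and markers of the other cell types that a spleen preparation could hold. Of these symbols, 6 were absent from the table, and 5 appeared more than once, for which the entry with the highest total was used. Lists with at least 5 tested members (44) were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Camera with the correlation estimated for each list, and fry, which tests whether the members of a list move on balance in one direction, were alternatives. Counts of members are also given adjusted over the list alone. Shares of counts held by 5 gene classes, and the total count, were compared by an exact two-sided permutation test over 252 assignments, adjusted over these 6 measures.

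The rule for named genes was also fixed beforehand. It takes the 12 largest increases and the 12 largest decreases among called protein-coding genes with a mean of at least 2 CPM, no predicted-gene symbol, and all 5 libraries of one group above all 5 of the other. It adds up to 4 members of each list with the smallest p, and a fixed set of B cell, cytokine, immunoglobulin and contamination marker genes whatever their values. The rule gave 202 tested genes, of which the text names those that describe each list; some of the genes in the rule's fixed set and lists are not reported here.

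The alternatives were other scalings (RLE, library size only, TMM without immunoglobulin and haemoglobin genes), no filter or a stricter filter on low counts (at least 1 CPM in at least 5 libraries), DESeq2 1.42.0, limma voom with quality weights, and limma on log2 of the deposited FPKM plus 1 or 0.1. Further alternatives were protein-coding genes alone, stricter thresholds, the replicate number as a block, and leaving out each library in turn. After the data were seen, 3 more were added: a fit without fibrosis libraries 4 and 5, an offset for each library's trend with GC content and length, and each library's erythroid score as a covariate. GC content came from GENCODE vM21 transcripts and was found for 99.9% of tested genes.

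The code was tested on simulated counts with the means and library sizes of this comparison, in which 200 of 14100 genes were changed. It recovered 52.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 96.9% of those changed 4-fold. Of 160 genes called in the simulation, 6.88% were unchanged. None (0) of 44 lists was called there. Genes were drawn independently of each other, so this does not test camera on lists whose members move together.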

Results

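RNA sequencing profiled splenic B cells from mice with liver fibrosis, induced by 4 weeks of carbon tetrachloride, and from wildtype mice, with 5 libraries in each group. The comparison asks how gene expression in splenic B cells differs between the fibrotic and the wildtype animals, and in particular whether the cells take on an inflammatory expression profile. The fibrosis libraries held between 13439100 and 17069393 counts and the control libraries between 15912080 and 17954551, and the total did not differ between groups (exact permutation p = 0.111, adjusted p = 0.167). Replicates correlated at 0.964 to 0.985 within the fibrosis group and at 0.986 to 0.991 within the control group, as Pearson's r of log2 CPM across genes, which are not independent replicates. No pair of libraries was close enough to be one library counted more than once (chi-square per degree of freedom of 5.40 or more).

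In fibrosis, 13 of 16 genes of class II antigen presentation, 11 of 19 costimulation genes, 13 of 17 marginal zone genes and 10 of 14 follicular genes were higher. All 26 S phase genes, all 26 G2 and M phase genes, 13 of 15 immature B cell genes and 14 of 20 erythroid genes were lower. As lists these passed camera with a preset correlation, but none (0) of 44 lists passed with an estimated correlation (8 at an unadjusted p under 0.05; 25 by fry). Of 14283 genes tested, 2654 were higher and 2451 lower in fibrosis at an adjusted p under 0.05 by edgeR's quasi-likelihood test. At least 2-fold changes made up 543 of the higher and 769 of the lower calls. The libraries of one group all lay above those of the other in 3506 called genes and in 3630 of all tested genes, where chance gives 0.794%. Higher genes were 52.0% of the calls with TMM scaling and 35.0% (1777 higher, 3306 lower) with library size only, which moved the median gene by -0.11 on the log2 scale. No call changed direction under that scaling.

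**Figure D1:**
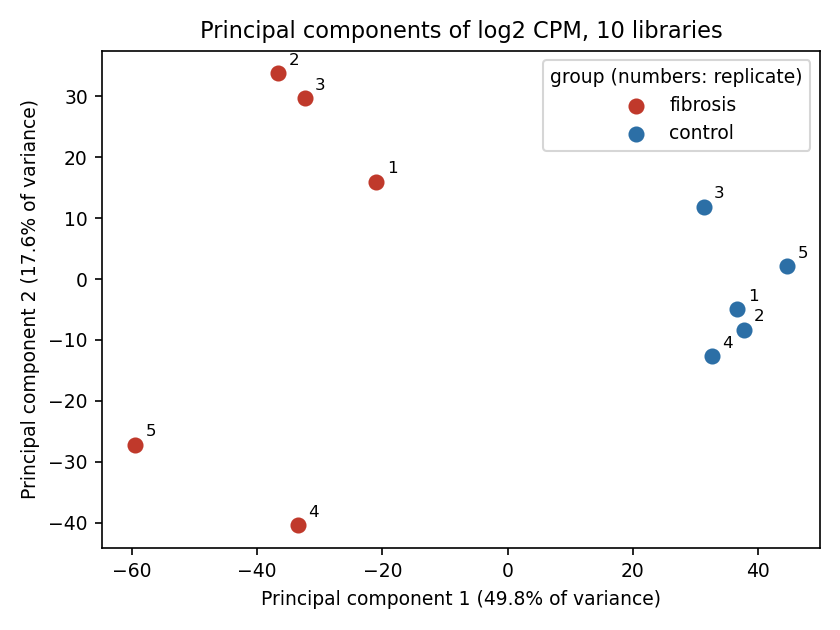
Each point is a library, placed by principal components 1 and 2 of log2 CPM over all tested genes (arbitrary units, share of variance on each axis), and coloured by group with its replicate number. Component 1 (49.8% of variance) parts the groups, and component 2 (17.6%) places fibrosis 4 and 5 at -40.4 and -27.2 and the other fibrosis libraries at 15.98 to 33.7.

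Fibrosis libraries 4 and 5 stood apart from the other fibrosis libraries on the second principal component. They held the highest levels of platelet, mitochondrially encoded, ribosomal protein and dendritic cell genes of all libraries. Without them, 2688 genes were higher and 2743 lower, and 82.4% of the calls above were made again in the same direction. This fit was added after the data were seen.

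Saa3, an acute-phase serum amyloid gene on chromosome 7 (46711998 to 46715700, minus strand, GRCm38), had the largest increase among the genes that the naming rule took for their fold change, 4.62 ± 0.60 on the log2 scale (SE; adjusted p = 0.00021 by edgeR). Its level was 24.1 ± 17.2 CPM in fibrosis and 0.965 ± 0.540 CPM in control (SD, n = 5 each). The other 11 increases taken by that rule lay between 2.16 and 2.43. They included the platelet genes Ppbp, Treml1 and Alox12, the secreted chaperone clusterin (Clu) and the semaphorin receptor gene Plxna4. The others were the secreted phospholipase gene Pla2g2d, and Mfap3l, Slc24a3, Cdc42ep5, Terb1 and Ctla2a. Among the fibrosis libraries, Clu, Plxna4, Mfap3l, Slc24a3, Cdc42ep5 and Ctla2a were lowest in fibrosis 1 and highest in fibrosis 4 or 5. The named platelet genes shared that pattern, so whether these rises lie in B cells is not settled here. Pla2g2d and Terb1 did not share it. Leaving out fibrosis 4 and 5 lowered Pla2g2d from 2.43 to 0.87 (adjusted p = 0.0758 by edgeR, over a range of 0.00204 to 0.145 across its alternatives) and Ctla2a from 2.16 to 1.23.

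The largest decrease taken by the naming rule was that of Ctrb1, the pancreatic chymotrypsinogen gene, at -5.47 ± 0.93, with 10 counts over the fibrosis libraries against 543 over the controls. Control 4 held 291 of these counts and was highest for other pancreatic genes too, so whether the fall of Ctrb1 lies in B cells is not settled here. The other 11 decreases taken by that rule lay between -3.32 and -2.60. Adam33, a metalloprotease gene on chromosome 2 (131050591 to 131063814), fell from 9.54 ± 1.77 to 0.969 ± 0.502 CPM (adjusted p = 1.35e-05 by edgeR). Sptb, which encodes the spectrin beta chain of the red cell membrane, fell from 385 ± 75.2 to 62.3 ± 29.1 CPM. The rest were the manganese transporter gene Slc30a10, the acyl-CoA synthetase gene Acsl6, the sodium pump subunit gene Atp1b2, the collagen gene Col5a3, the RNA-binding protein gene Igf2bp3, and St5, Podxl, Cachd1 and Prss50. Sptb, Podxl, Atp1b2, Prss50, St5 and Slc30a10 were lowest in fibrosis 2 and 5, the libraries with the lowest erythroid levels (18.2% and 22.3% of the control mean). Whether these falls lie in B cells is thus not settled here. The other decreases taken by that rule did not have this order. Among them, Adam33, Acsl6 and Cachd1 were highest among the fibrosis libraries in fibrosis 4, which held the highest erythroid level there (59.6%). Their source is therefore not settled either. Col5a3 and Igf2bp3 were lowest in fibrosis 4.

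**Figure D2:**
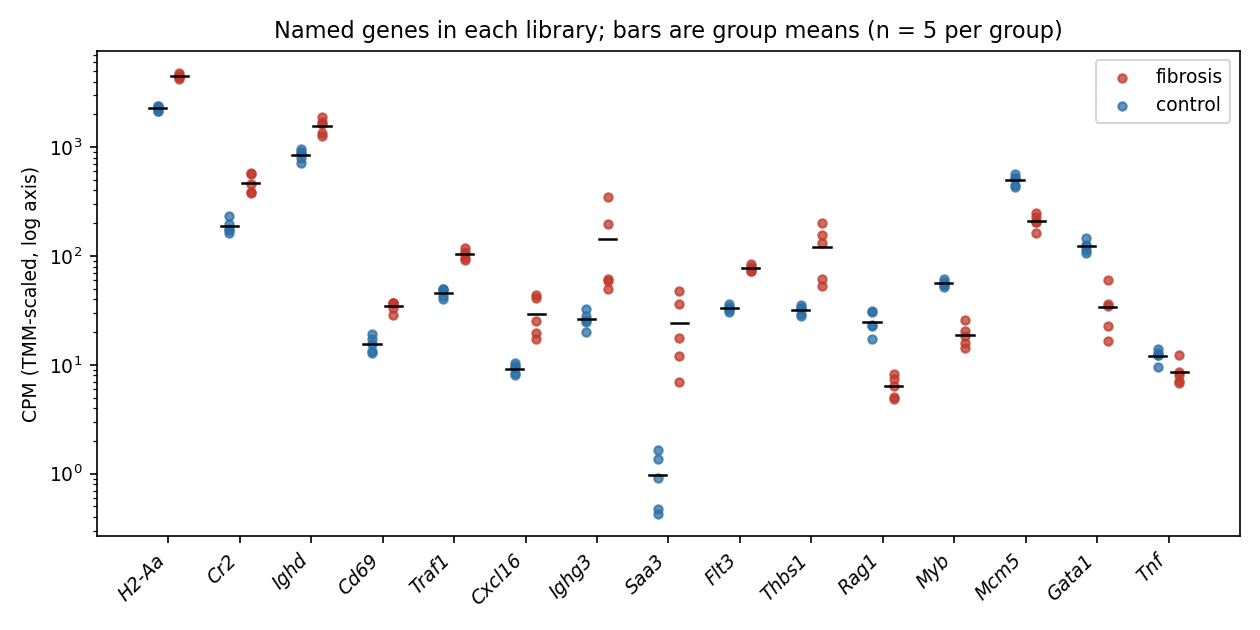
CPM (TMM-scaled, log axis) of 15 named genes, with a point for each of the 5 fibrosis and 5 control libraries and a bar at each group mean. H2-Aa, Cr2, Traf1 and Flt3 lie higher in every fibrosis library than in any control library, Rag1, Myb, Mcm5 and Gata1 lie lower, and Tnf overlaps between groups.

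Of 44 gene lists tested by camera with the preset correlation, 20 were higher and 4 lower in fibrosis. With the correlation estimated for each list, none (0) passed after adjustment (lowest adjusted p = 0.0601), 8 had an unadjusted p under 0.05, and fry called 25 lists, 22 of them among those of the preset test. The number of lists is no larger than chance can give, since 20 of 100 splits of the 10 libraries, the labelled one included, called at least 24 lists. The list results below therefore rest on their members, whose calls come from the gene test.

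Of 16 tested genes of antigen presentation by class II molecules, 13 were higher, 14 adjusted over the list alone, and none (0) lower. The median of the list was 0.65 (adjusted p = 1.55e-09 by camera; adjusted p = 0.0601 with an estimated correlation). H2-Aa, the alpha chain gene of the class II molecule I-A on chromosome 17 (34282744 to 34287827), rose from 2264 ± 114 to 4494 ± 212 CPM, a log2 change of 0.99 ± 0.08 (adjusted p = 1.34e-05 by edgeR). Its partner chain gene H2-Ab1 rose by 0.89 ± 0.09, and H2-Oa and H2-DMb1, which act in peptide loading, rose by 0.90 ± 0.09 and 0.78 ± 0.08. Class II genes are also expressed by dendritic cells, whose markers were higher in these libraries.

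Costimulation and activation markers were higher in 11 of 19 members, 13 adjusted over the list alone, with 1 lower. They included the early activation antigen Cd69 (1.15 ± 0.13), the tumour necrosis factor receptor family gene Tnfrsf9 (1.74 ± 0.26), the ligand gene Icosl (0.82 ± 0.12) and Cd40 (0.54 ± 0.07), the receptor through which T cells help B cells. T, NK and dendritic cells also express genes of this list, and their markers were higher in the same libraries. The list had an adjusted p of 0.000453 by camera and an adjusted p of 0.0601 with an estimated correlation. Cd80 (0.55 ± 0.18) and Cd86 (0.51 ± 0.17), which costimulate T cells through Cd28, passed in the full set, but without fibrosis 4 and 5 they were at 0.25 and 0.21 (adjusted p = 0.210 and 0.0900 by edgeR). Their adjusted p ranged from 0.0155 to 0.210 and from 0.00210 to 0.121 over all alternatives. Cd80 also lost its call without fibrosis 4 or 5 or control 1, 2, 3 or 5 (0.42 to 0.57, adjusted p from 0.0547 to 0.0837 by edgeR). Cd86 lost its call without fibrosis 4 or 5 or control 2, 3 or 5 (0.33, without fibrosis 5, to 0.52, adjusted p from 0.0511 to 0.0619 by edgeR).

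NF-kB targets were higher in 16 of 28 members, 18 adjusted over the list alone, with 1 lower. Traf1, an adaptor of tumour necrosis factor receptors, rose from 46.1 ± 4.46 to 104 ± 10.96 CPM, and Relb, a subunit of the non-canonical NF-kB pathway, rose by 0.67 ± 0.07. The iron transporter gene Slc11a2 was the member that fell, at -1.30 ± 0.13, and erythroid markers fell in the same libraries. Dendritic, T and NK cell markers were higher in them, so the source of the rise is not settled here. The list had an adjusted p of 6.90e-05 by camera and an adjusted p of 0.0794 with an estimated correlation.

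Inflammatory cytokines and chemokines were higher in 9 of 22 members, 12 adjusted over the list alone, with a median of 0.61 (adjusted p = 0.00186 by camera; adjusted p = 0.468 with an estimated correlation). The median was 0.40 without fibrosis 4 and 5 (adjusted p = 0.0282 by camera), and the neutrophil, macrophage, T cell, NK cell, dendritic cell and platelet markers, whose cells also express cytokines and chemokines, were highest in those libraries. Il1b was at 107 and 105 CPM in fibrosis 4 and 5 and S100a8 at 1385 and 1969 CPM, against at most 41.9 and 347 CPM in the other fibrosis libraries. Cxcl16, a chemokine for Cxcr6-bearing lymphocytes, rose by 1.67 ± 0.25, Ccl5 by 1.05 ± 0.19, the lymphotoxin gene Ltb by 0.60 ± 0.09 and Il16 by 0.53 ± 0.09. Tnf was the lower member, at -0.49 ± 0.17 (adjusted p = 0.0383 by edgeR), and it lost its call without fibrosis 1, 2 or 4 or control 1, 3, 4 or 5 (-0.50 to -0.42, adjusted p from 0.0545 to 0.0937; 0.00430 to 0.0937 over all alternatives). Il1b stood at 1.02 ± 0.40 with an adjusted p of 0.0691 by edgeR. It passed without fibrosis 2 or 3 (1.18 and 1.17, adjusted p = 0.0486 and 0.0416) and was at 0.15 without fibrosis 4 and 5 (adjusted p = 0.657). Il6 and Il10 were too low to test, with 9 and 23 counts over all fibrosis libraries and 3 and 11 over all controls, so a difference in either was not detectable at this depth. Tgfb1 was at -0.06 ± 0.11 (adjusted p = 0.709 by edgeR).

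Interferon-gamma-induced genes were higher in 10 of 28 members, 10 adjusted over the list alone, with 1 lower (adjusted p = 0.00185 by camera; adjusted p = 0.562 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 0.91 ± 0.13, the guanylate-binding protein gene Gbp3 by 0.80 ± 0.12, the immunoproteasome gene Psmb8 by 0.67 ± 0.10 and Irf8, which is also on the dendritic cell list, by 0.55 ± 0.09. The mean of the list relative to control was 0.21 in fibrosis 1 and -0.073 in fibrosis 3, both below control 3 (0.23). Dendritic, T and NK cell markers were also higher in the fibrosis group, and with the erythroid covariate the list's median was -0.094 (adjusted p = 0.260 by camera). Type I interferon-stimulated genes did not pass as a list (adjusted p = 0.274 by camera; 0.0189, lower, without fibrosis 2; 9.10e-11 to 0.903 over all alternatives), with 2 of 43 members higher and 7 lower, and 1 and 4 adjusted over the list alone. Among them Ly6a rose by 1.25 ± 0.13, while Cmpk2 and Isg20 fell by 1.12 and 1.18. Isg20 was highest among the fibrosis libraries in fibrosis 4 and lowest in fibrosis 2 and 5, as the erythroid markers were. With the erythroid covariate the type I list passed as lower (adjusted p = 9.10e-11 by camera).

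**Figure D3:**
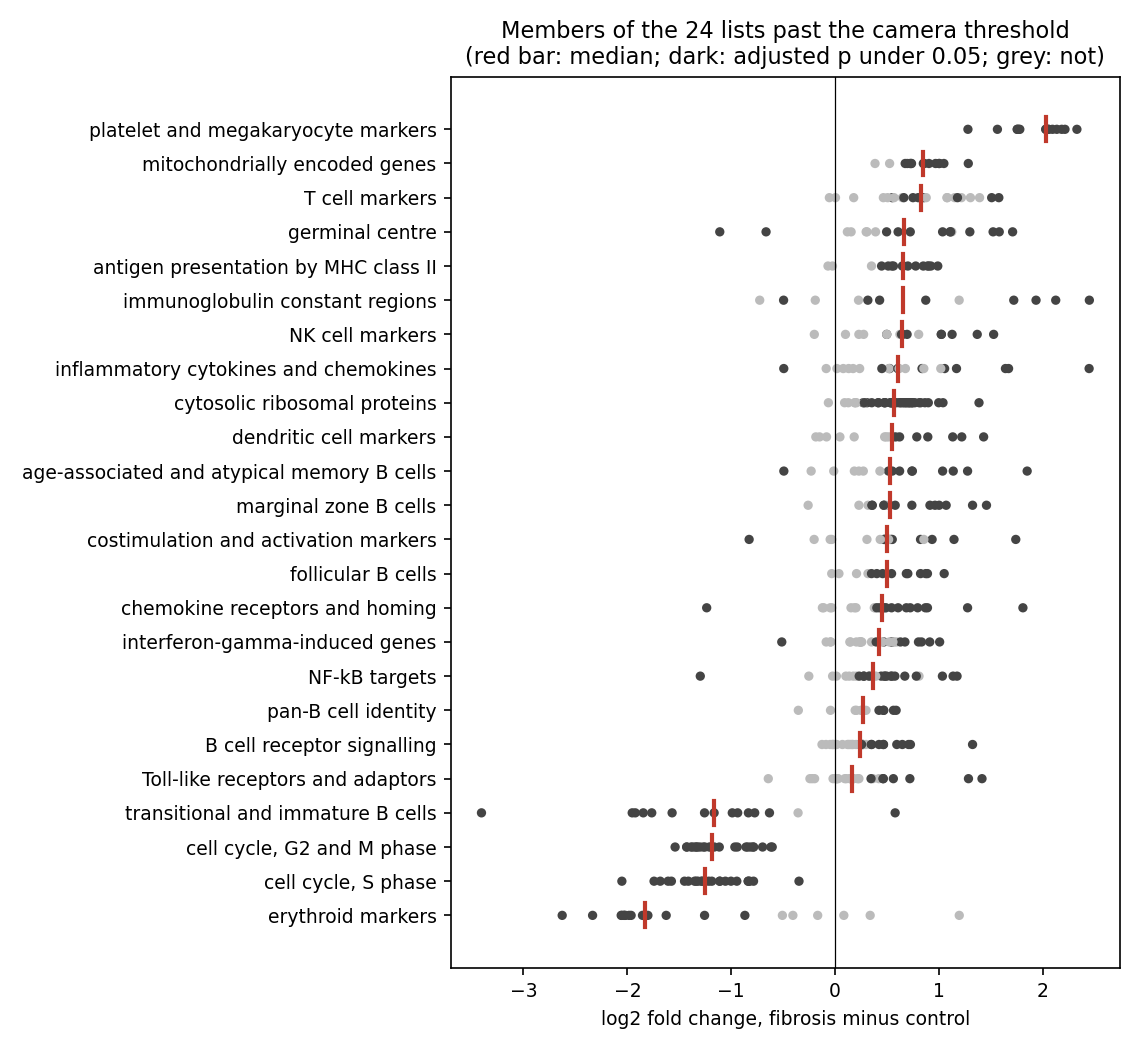
Log2 fold change (fibrosis minus control, horizontal axis) of each tested member of the 24 lists past the camera threshold with the preset correlation, one list per line. Dark points passed the gene test, grey points did not, and the red bar is the median of the list, from -1.83 for erythroid markers to 2.03 for platelet and megakaryocyte markers.

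Genes of mature B cell subsets were higher. The mean of the follicular list relative to control was 0.59, 0.70, 0.70, 0.22 and 0.29 in fibrosis 1 to 5. That of the B cell identity list was 0.36, 0.50, 0.43, -0.066 and 0.040. A larger share of B cells may thus account for part of the follicular rise, which was not tested. The marginal zone list stayed at 0.44 and 0.78 in fibrosis 4 and 5. Of 17 marginal zone genes, 13 were higher, 14 adjusted over the list alone, where 1 was also lower. Cr2, the complement receptor CD21 on chromosome 1 (195136811 to 195176716), rose from 189 ± 27.5 to 473 ± 96.0 CPM, and the Notch target Dtx1, Cd9 and Fcrl5 rose by 0.96 ± 0.14, 1.46 ± 0.25 and 0.74 ± 0.11. Cd9, which platelets also express, was at 0.95 without fibrosis 4 and 5. The list had an adjusted p of 1.69e-06 by camera and an adjusted p of 0.188 with an estimated correlation. Of 14 follicular genes, 10 were higher, 10 adjusted over the list alone (adjusted p = 7.77e-05 by camera; adjusted p = 0.413 with an estimated correlation). Ighd, the immunoglobulin D heavy chain gene, rose by 0.87 ± 0.13 and the complement regulator gene Cd55 by 1.05 ± 0.17. Fcer2a, the CD23 gene, was at 0.32 ± 0.14 (adjusted p = 0.102 by edgeR), and passed without fibrosis 4 or 5 (0.40 and 0.39, adjusted p = 0.0333 and 0.0456; 0.00137 to 0.398 over all alternatives).

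Age-associated and atypical memory genes were higher in 9 of 16 members, 9 adjusted over the list alone, with 1 lower (adjusted p = 0.000927 by camera; adjusted p = 0.366 with an estimated correlation). The transcription factor gene Tbx21 rose by 1.14 ± 0.16, its target Cxcr3 by 1.28 ± 0.17, the integrin gene Itgax by 0.62 ± 0.08 and the ectonucleotidase gene Nt5e by 1.85 ± 0.25. Tbx21 and Cxcr3 are also expressed by T and NK cells, and Itgax is on the dendritic cell list. The markers of these cell types were higher in the same libraries (medians of 0.83, 0.65 and 0.55), so the source of the change is not settled here. The median of this list was 0.53, and 0.23 without fibrosis 4 and 5 (adjusted p = 0.0156 by camera). Germinal centre genes were higher in 10 and lower in 2 of 18 members, 13 and 2 adjusted over the list alone (adjusted p = 0.00403 by camera; adjusted p = 0.366 with an estimated correlation). Gcsam rose by 1.58 ± 0.22. Gpr183, which guides B cells in the follicle, rose by 0.61 ± 0.07, which does not by itself mark germinal centre cells. The 2 lower members were Ung, an enzyme of DNA repair that is also on the S phase list, at -1.11, and Ezh2 at -0.66. Chemokine receptor and homing genes were higher in 13 of 24 members, 13 adjusted over the list alone (adjusted p = 0.000479 by camera, and adjusted p = 0.188 with an estimated correlation). Itgae rose by 1.81 ± 0.19 and Cx3cr1, which is also on the macrophage list, was lower at -1.24 ± 0.16. As T, NK and dendritic cell markers were higher in the same libraries, the source of these changes is not settled here either.

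Of 14 B cell identity genes, 5 were higher, 9 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0441 by camera; adjusted p = 0.723 with an estimated correlation), and the list lost its call without fibrosis 1, 2 or 3 or control 1, 2, 4 or 5 (adjusted p from 0.0558 to 0.134; 1.88e-05 to 0.723 over all alternatives). Without fibrosis 4 and 5 the median was 0.45 and 12 of 14 members were higher (adjusted p = 1.88e-05 by camera), while the mean of the list relative to control was -0.066 and 0.040 in fibrosis 4 and 5. Ptprc, Cd74 and Ms4a1 rose by 0.59 ± 0.13, 0.56 ± 0.13 and 0.47 ± 0.12. Cd74 lost its call with FPKM without a filter (0.52, adjusted p = 0.480; 0.000232 to 0.480 over all alternatives). Cd22 was at 0.42 ± 0.14 (adjusted p = 0.0343 by edgeR), lost its call without fibrosis 1, 2 or 3 or control 1, 2, 4 or 5 (0.35 to 0.42, adjusted p from 0.0697 to 0.0978), and was at 0.64 without fibrosis 4 and 5 (adjusted p = 9.81e-05; up to 0.200 over all alternatives). Cd79a was at 0.30 ± 0.13 (adjusted p = 0.0886 by edgeR), and passed without fibrosis 4 or 5 (0.36 and 0.38, adjusted p = 0.0451 and 0.0216; 0.000471 to 0.510 over all alternatives). B cell receptor signalling genes were higher in 13 of 32 members, 14 adjusted over the list alone (adjusted p = 0.00181 by camera; adjusted p = 0.562 with an estimated correlation), among them the inhibitory Fc receptor gene Fcgr2b at 0.65 ± 0.09 and Malt1 at 0.71 ± 0.12. The mean of this list relative to control was 0.29, 0.42 and 0.30 in fibrosis 1, 2 and 3. That did not exceed the B cell identity list, at 0.36, 0.50 and 0.43. Toll-like receptors and adaptors were higher in 7 of 27 members, 7 adjusted over the list alone (adjusted p = 0.0199 by camera; adjusted p = 0.366 with an estimated correlation), with Tlr3 up by 1.41 ± 0.16, Tlr11 by 1.28 ± 0.17 and the inhibitory kinase gene Irak3 by 0.72 ± 0.09. Cross-presenting dendritic cells, whose markers were also higher, express Tlr3 and Tlr11. Tlr4 was at 0.36 ± 0.18 (adjusted p = 0.140 by edgeR; 0.48 and 0.0355 without fibrosis 1; 0.0355 to 0.691 over all alternatives).

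Immunoglobulin constant region genes were higher in 7 and lower in 1 of 12 members, 9 and 1 adjusted over the list alone. The switched isotypes rose most, with Ighg3 at 2.45 ± 0.55, Ighg2c at 2.12 ± 0.50, Ighg2b at 1.93 ± 0.44 and Igha at 1.72 ± 0.38, while Ighg1 stood at 1.19 ± 0.45 (adjusted p = 0.0569 by edgeR; 1.47 and 0.0339 without control 1; 0.0339 to 0.222 over all alternatives). The rise of Ighg3 was uneven, at 350 and 196 CPM in fibrosis 1 and 2, 49.4 to 61.2 CPM in the other fibrosis libraries and 20.1 to 32.2 CPM in the controls. Ighg2c lost its call without a filter on low counts (adjusted p = 0.0514 by edgeR). Ighm was at -0.19 ± 0.16 (adjusted p = 0.369 by edgeR), and the light chain gene Iglc1 fell by 0.50. The list had an adjusted p of 0.0199 by camera, an adjusted p of 0.468 with an estimated correlation and an adjusted p of 0.0525 without fibrosis 1. With the offset for GC content and length its adjusted p was 0.152, over a range of 7.38e-05 to 0.468 across the alternatives. Immunoglobulin genes together held 1.36% ± 0.326 of counts in fibrosis and 1.30% ± 0.0922 in control (exact permutation adjusted p = 0.881). Plasma cell and antibody secretion genes did not pass as a list (adjusted p = 0.362 by camera), with 3 of 24 members higher and 1 lower and 2 higher adjusted over the list alone; Mzb1 was higher by 0.58 ± 0.09 and the joining chain gene Jchain was at 0.30 ± 0.21.

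Cell cycle genes were lower in every tested member, and erythroid markers, whose cells also divide, fell in the same libraries. With the erythroid level as a covariate the group difference of the cell cycle level went from -54.3 to -22.1 percentage points of the control level. All 26 S phase genes fell, 26 also adjusted over the list alone, with a median of -1.25 (adjusted p = 2.77e-32 by camera; adjusted p = 0.0959 with an estimated correlation). Mcm10, a replication factor gene on chromosome 2 (4989714 to 5012791), fell from 69.8 ± 7.10 to 20.9 ± 3.65 CPM, Uhrf1 from 329 ± 43.8 to 110 ± 21.3 CPM, and Mcm5, a subunit of the replicative helicase, from 499 ± 55.5 to 210 ± 32.4 CPM. All 26 G2 and M phase genes fell, 26 also adjusted over the list alone, with a median of -1.19 (adjusted p = 8.72e-28 by camera; adjusted p = 0.102 with an estimated correlation), including the mitotic checkpoint gene Bub1b at -1.25 ± 0.11 and the anaphase activator gene Cdc20 at -1.30 ± 0.12. No planned scaling, filter, tool or left-out library turned the direction of any of these calls.

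Transitional and immature B cell genes fell in 13 and rose in 1 of 15 members, 14 and 1 adjusted over the list alone, with a median of -1.16 (adjusted p = 3.42e-09 by camera; adjusted p = 0.0601 with an estimated correlation). Rag1, the recombinase of antigen receptor genes on chromosome 2 (101638282 to 101649501), fell from 24.9 ± 5.70 to 6.40 ± 1.45 CPM. The progenitor transcription factor genes Myb and Sox4 fell by 1.57 and 1.26 on the log2 scale, and Cd24a, which immature B cells carry at high levels, fell by 0.99. Myb and Cd24a are also expressed by red cell precursors, whose markers were lower in the same libraries.

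Erythroid markers fell in 14 of 20 members, 14 adjusted over the list alone, with a median of -1.83 (adjusted p = 3.97e-08 by camera; adjusted p = 0.366 with an estimated correlation). The erythroid transcription factor gene Gata1 fell from 123 ± 15.4 to 34.0 ± 16.8 CPM, the membrane protein gene Ermap by 2.33 and the carbonic anhydrase gene Car2 from 1105 ± 189 to 271 ± 146 CPM. The beta-globin gene Hbb-bs did not pass, at 0.34 ± 0.62, with 992 ± 1019 CPM in fibrosis and 784 ± 166 CPM in control. It was at -0.43 without fibrosis 4, and also negative with voom, with FPKM and with the replicate block. Leaving out fibrosis 4 and 5 put it at -1.22, called lower like the other erythroid markers (adjusted p = 0.0262 by edgeR; up to 0.857 over all alternatives). Haemoglobin genes held 0.239% ± 0.234 of counts in fibrosis and 0.261% ± 0.0497 in control (exact permutation adjusted p = 0.881). Mean erythroid marker levels without the globins and Tfrc were 18.2% to 59.6% of the control mean in the fibrosis libraries, and mean cell cycle levels were 37.0% to 55.4%.

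**Figure D4:**
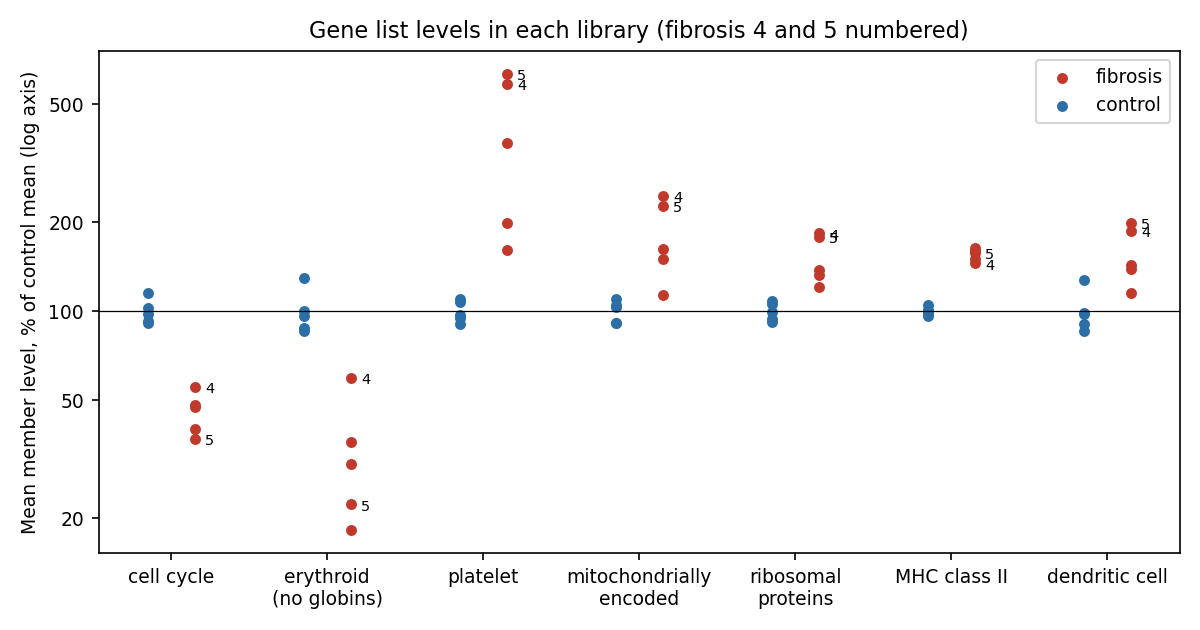
Mean level of each gene list in each library as a percentage of the control mean (log axis, members weighted equally), one point per fibrosis or control library, with fibrosis 4 and 5 numbered. Cell cycle and erythroid levels lie below every control library in all fibrosis libraries, and the platelet level reaches 584% and 635% in fibrosis 4 and 5 against 161% to 370% in the other fibrosis libraries.

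Platelet and megakaryocyte markers rose in all 15 tested members, 15 also adjusted over the list alone, with a median of 2.03 (adjusted p = 5.83e-09 by camera; adjusted p = 0.366 with an estimated correlation). Ppbp rose from 26.8 ± 5.38 to 135 ± 84.8 CPM. Without fibrosis 4 and 5 the median was 1.39. Endothelial markers did not pass as a list (adjusted p = 0.373 by camera), with 4 of 11 members higher and 2 lower, 4 and 2 adjusted over the list alone. Vwf, which megakaryocytes also express, rose by 1.27 ± 0.30 and was at 0.70 without fibrosis 4 and 5 and not called with FPKM without a filter (adjusted p = 0.0532; from 2.49e-05 over all alternatives). The endothelial gene Plvap fell by 1.16.

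Dendritic cell markers were higher in 8 of 17 members, 8 adjusted over the list alone (adjusted p = 6.90e-05 by camera; adjusted p = 0.366 with an estimated correlation). Flt3, the receptor for the dendritic cell growth factor Flt3 ligand, on chromosome 5 (147330741 to 147400489), rose from 33.2 ± 2.16 to 77.3 ± 5.00 CPM, and Xcr1 and Clec9a, markers of cross-presenting dendritic cells, rose by 1.43 ± 0.13 and 1.13 ± 0.19. T cell markers were higher in 8 of 22 members, 9 adjusted over the list alone (adjusted p = 0.00199 by camera; adjusted p = 0.585 with an estimated correlation), with Cd2 up by 0.55 ± 0.09 and the signalling adaptor gene Lat by 1.58 ± 0.32. Cd3e was at 1.39 ± 0.58 (adjusted p = 0.0787 by edgeR; 1.66 and 0.0123 without fibrosis 3; 0.00155 to 0.623 over all alternatives). NK cell markers were higher in 9 of 16 members, 9 adjusted over the list alone (adjusted p = 0.00403 by camera; adjusted p = 0.562 with an estimated correlation), with Klrk1 up by 1.13 ± 0.21 and Xcl1 by 1.53 ± 0.26. Without fibrosis 4 and 5 the T and NK cell lists had medians of 0.26 and 0.43 and no longer passed (adjusted p = 0.0558 and 0.0672 by camera). Lat was then at 0.94 and Cd3e at 0.37. Cd2 did not follow them, at 0.66 without those libraries (adjusted p = 5.32e-05 by edgeR), so its rise need not come from T cells.

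Macrophage and monocyte markers did not pass (1 of 25 higher, 1 lower; 0 and 1 adjusted over the list alone; adjusted p = 0.643 by camera), and their median, 0.06, and the direction of the test differed in sign. Without fibrosis 4 and 5 they were lower, with a median of -0.80 (adjusted p = 8.65e-06 by camera, over a range up to 0.992 across the alternatives). Marco, a scavenger receptor gene of marginal zone macrophages, was at 2.32 ± 0.78 (adjusted p = 0.0398 by edgeR) and at 0.94 without those libraries, and lost its call without fibrosis 3, 4 or 5 or control 1, 3, 4 or 5 (1.73 to 2.38, adjusted p from 0.0546 to 0.126; up to 0.359 over all alternatives). Lyz2 was at -0.53 ± 0.27 (adjusted p = 0.148 by edgeR). None (0) of 20 neutrophil markers passed by edgeR or adjusted over the list alone, with S100a8 at 1.84 ± 0.78 (adjusted p = 0.0919 by edgeR; 2.09 and 0.0391 without fibrosis 3; up to 0.868 over all alternatives; list adjusted p = 0.840 by camera). Mast cell, basophil and eosinophil markers did not pass as a list (adjusted p = 0.465 by camera), with 3 of 9 higher and none (0) adjusted over the list alone, and Prss34, at 2.01 ± 0.67, lost its call without fibrosis 2, 4 or 5 or control 1, 2 or 5 (1.57 to 2.02, adjusted p from 0.0534 to 0.0824; 0.00236 to 0.166 over all alternatives). None (0) of 5 tested stromal and fibroblast markers passed by edgeR or adjusted over the list alone (list adjusted p = 0.788 by camera).

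Cytosolic ribosomal protein genes rose in 39 of 46 members, 40 adjusted over the list alone, with a median of 0.57 (adjusted p = 1.77e-11 by camera; adjusted p = 0.443 with an estimated correlation), led by Rps27 at 1.39 ± 0.18 and Rpl23 at 0.81 ± 0.14. Their share of counts was 8.36% ± 1.26 in fibrosis and 6.15% ± 0.360 in control (exact permutation adjusted p = 0.0238). Mitochondrially encoded genes rose in 13 of 15 members, 14 adjusted over the list alone, with a median of 0.85 (adjusted p = 2.88e-05 by camera; adjusted p = 0.443 with an estimated correlation), including the cytochrome oxidase gene mt-Co1 at 0.72 ± 0.15. The call of mt-Co1 was lost with FPKM without a filter (adjusted p = 0.168; from 9.76e-06 over all alternatives). Their share was 1.63% ± 0.404 in fibrosis and 1.03% ± 0.0980 in control (exact permutation adjusted p = 0.0317). Both shares were highest in fibrosis 4 and 5, at 9.86% and 9.54% for ribosomal protein genes and 2.003% and 2.04% for mitochondrially encoded genes, the libraries with the highest platelet levels. Without those libraries the ribosomal protein list had a median of 0.39, with 37 of 46 members higher (adjusted p = 2.58e-11 by camera). The mitochondrial list then had a median of 0.49 (adjusted p = 0.000919 by camera), and with the offset for GC content and length it no longer passed (adjusted p = 0.126 by camera). The 100 most abundant genes held 23.7% ± 1.53 of counts in fibrosis and 19.1% ± 0.696 in control (exact permutation adjusted p = 0.0238). Without control 5 the adjusted p of these 3 shares was 0.0595, and without control 1, 2 or 4 that of the mitochondrial share was 0.0794.

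The lists for regulatory B cells, the BAFF and APRIL axis, B1 cells, apoptosis, profibrotic factors and complement did not pass camera with the preset correlation. Fry called 3 of them, regulatory B cells (adjusted p = 0.0128), the BAFF and APRIL axis (adjusted p = 0.000736) and apoptosis (adjusted p = 0.0357). Regulatory B cell genes were higher in 5 and lower in 1 of 15 members, 5 and 1 adjusted over the list alone (adjusted p = 0.318 by camera). The BAFF and APRIL axis was higher in 4 of 13 members, 4 adjusted over the list alone (adjusted p = 0.0998 by camera), with Bcl2 at 0.54 ± 0.13 and the BAFF receptor gene Tnfrsf13c at 0.03 ± 0.12 (adjusted p = 0.883 by edgeR). This list passed camera without fibrosis 4 and 5 (adjusted p = 0.0465) and with the offset for GC content and length (adjusted p = 0.0163). B1 cell genes were higher in 2 and lower in 4 of 14 members, 3 and 4 adjusted over the list alone (adjusted p = 0.608 by camera), with Sox12 down by 1.13 ± 0.12 and Spn by 0.77 ± 0.13. Genes of apoptosis were higher in 8 and lower in 4 of 24 members, 8 and 4 adjusted over the list alone (adjusted p = 0.259 by camera), with the pro-apoptotic Pmaip1 up by 1.15 ± 0.17 and the anti-apoptotic Bcl2a1d up by 1.14 ± 0.21, which was at 0.73 without fibrosis 4 and 5. Profibrotic factors were higher in 3 and lower in 2 of 17 members, 3 and 2 adjusted over the list alone (adjusted p = 0.706 by camera). Thbs1 and Ltbp1, which act in the release and storage of latent TGF-beta and which platelets also carry, rose by 1.92 ± 0.33 and 1.99 ± 0.32, and the fibronectin gene Fn1 fell by 1.19. Complement genes were higher in 5 and lower in 1 of 17 members, 6 and 1 adjusted over the list alone (adjusted p = 0.166 by camera). The balance of the last 2 lists rested on fibrosis 4 and 5. Leaving these out gave 3 higher and 4 lower profibrotic genes and a median of -0.21 (0.27 with all libraries), and 4 higher and 7 lower complement genes and a median of -0.14 (0.25 with all libraries).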

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

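Only the counts of regrouped libraries were fixed before the result was seen; the tests of erythroid, platelet and dendritic cell levels, of the B cell share and of GC content and length were chosen after it. The labelled groups called 5105 genes, and the highest other of 100 splits of the 10 libraries called 1. Only 1 of the 100, the labelled split, reached that count, which argues against chance assignment of these libraries. The labels do not say that the libraries came from separate animals, so chance differences between animals or preparations are not excluded. For gene lists chance cannot be excluded: the labelled groups called 24, 20 of 100 splits called as many, and the highest other called 29.

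The cell cycle genes fell in every member. Their mean level was lower by 54.3 percentage points of the control level, and with each library's erythroid marker level (globins and Tfrc left out) as a covariate the group difference was -22.1 (95% interval -31.8 to -12.4), with a slope of 0.483 (0.3502 to 0.616). Fewer red cell precursors, whose most abundant marker besides the globins, Car2, was at 271 against 1105 CPM, may account for part or all of the fall. Erythroid levels did not overlap between the groups, at 18.2% to 59.6% of the control mean in fibrosis and 86.0% to 130% in control. The group term therefore rests on extrapolation, and this fit cannot say how much of the fall they explain. GC content and gene length are argued against, since the difference in mean log2 CPM was -1.21 after the offset and -1.19 before (exact permutation p = 0.00794). The erythroid score separates the groups, so a fit that holds it as a covariate has little power: edgeR then called 0 genes, with 1491 at an unadjusted p under 0.05. Of the 24 lists, 17 kept their call, S phase among them (adjusted p = 1.26e-14 by camera). That test used the preset correlation of 0.01, where the estimate for the S phase list without the covariate was 0.642. The lists that lost it were B cell identity and B cell receptor signalling (both 0.209), interferon-gamma (0.260), Toll-like receptors (0.645), immunoglobulin constant regions (0.107), germinal centre (0.558) and erythroid markers (0.533). Cholesterol biosynthesis (0.00649) passed camera with this covariate only. Type I interferon (9.10e-11) and macrophage markers (0.0261) passed camera with it but not in the main test. Type I interferon also passed camera without fibrosis 2 (0.0189), and macrophage markers without fibrosis 4 and 5 (8.65e-06). A lower share of cycling or immature B cells stays open, untested.

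The ribosomal protein and mitochondrially encoded genes rose, most in fibrosis 4 and 5. With the platelet level as a covariate the group difference of ribosomal protein genes was 19.6 points (-9.64 to 48.8) against 50.7 without it, and that of mitochondrially encoded genes 8.93 (-20.4 to 38.3) against 79.5. More platelet and megakaryocyte RNA may thus account for the mitochondrial rise and for part of the ribosomal one (Itga2b, the most abundant marker, was at 278 against 63.4 CPM). In fibrosis 1, 2 and 3 platelet levels were 161%, 198% and 370% of the control mean, but ribosomal protein levels were 138%, 132% and 121%. The ribosomal fit therefore leans on fibrosis 4 and 5. Platelet levels did not overlap between the groups, at 161% to 635% in fibrosis and 90.9% to 110% in control, so both group terms rest on extrapolation. Macrophage, neutrophil, T and NK cell markers were also highest in fibrosis 4 and 5, so these fits cannot single out platelets. GC content and length are argued against for the ribosomal protein genes, at 0.53 after the offset and 0.54 before (exact permutation p = 0.00794). For the mitochondrially encoded genes they cannot be told apart from the groups, since the difference went from 0.76 to 0.17 after the offset but kept its sign (exact permutation p = 0.0238). How the cells were isolated is not given in the sources used here, so a step that would remove platelets is not known. RNA quality was not tested.

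The class II genes rose by 0.59 as a list without Cd74. A larger share of B cells is argued against as the whole cause, since the class II list minus the B cell identity list was 0.36 higher in fibrosis (exact permutation p = 0.00794, the smallest that these assignments can give). That gap was largest in fibrosis 4 and 5 (0.62 and 0.63), and without them it was 0.18 (exact permutation p = 0.0357) while the B cell identity list was 0.41 higher, so a larger share of B cells may account for much of the rise in fibrosis 1, 2 and 3. The dendritic cell level left out Bst2, Irf8, Ly6d and Itgax, since B cells express them. With it as a covariate the group difference was 55.5 points (41.4 to 69.6) against 55.2 without it. The slope was -0.0059 (-0.194 to 0.182), so this level did not track the class II level. The markers Flt3 (77.3 against 33.2 CPM), Xcr1 (26.5 against 9.82) and Clec9a (22.7 against 10.3) were higher. The most abundant marker kept, Sirpa, which macrophages also express, was not (312 against 346). Without fibrosis 4 and 5, Flt3 and Xcr1 were still higher, by 1.22 and 1.31 on the log2 scale. More dendritic cells as a cause are therefore not decided by this fit. Higher class II expression within B cells, or more mature B cells among them, stays a hypothesis and was not tested.

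Single libraries lay far from the rest of their group in 21 of the groups tested, as the gap to the nearest library divided by the group's range; chance gives about 1 in 20, or 19.3. In control 3 these were Bcl2 (0.759), Ddx3y (0.767), Malt1 (0.745), Ms4a1 (0.733) and the lists for B cell identity (0.816), B cell receptor signalling (0.800), NRF2 and xenobiotic response (0.7499) and sex-linked genes (0.801). In control 2 they were Marco (0.721) and Nt5e (0.844), in control 4 Ltb (0.759) and the list of inflammatory cytokines (0.847), and in control 5 Atf4 (0.788), Car2 (0.810) and Gclc (0.720). In the fibrosis group they were Fn1 in fibrosis 1 (0.824), Prss34 (0.748) and Psmb8 (0.722) in fibrosis 3, Isg20 (0.778) and the total count (0.795) in fibrosis 4, and St5 in fibrosis 5 (0.884).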

How the results depend on the processing

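The alternatives without fibrosis 4 and 5, with the GC and length offset and with the erythroid covariate were chosen after the data were seen. No planned scaling, filter, tool or left-out library changed the sign of a called gene. Of 178 called genes that the naming rule gave, 162 kept their call in all 10 fits that left out 1 library, 165 without fibrosis 4 and 5, and 135 in each of 12 other scalings, filters, tools and the block, where the 23 that were not tested in some of these count as lost. Leaving out 1 library gave 2052 to 2914 higher genes, 2083 to 2582 lower genes, 22 to 25 lists and 0 to 3 composition measures, with 0 without control 5 (3 with all libraries). Other scalings, filters and tools stayed within 1.5 times the main counts except FPKM without a filter, at 1742 higher genes. Stricter thresholds gave 1547 higher genes at an adjusted p under 0.01, and 543 higher and 769 lower genes with a fold change of at least 2. The estimated correlation gave 0 lists, 8 with an unadjusted p under 0.05. The erythroid covariate gave 0 higher and 0 lower genes, with 1491 at an unadjusted p under 0.05 by edgeR, the only tool run with it; 209 of the called genes changed sign, and the GC and length offset changed 11.

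The libraries were treated as sharing only a number, since no label ties equal numbers together and same-numbered libraries had residual correlations of 0.11, -0.12, 0.40, 0.25 and -0.24, not all positive. In 3 of 5 fibrosis libraries the best match was the control of the same number, so a shared day or litter for some of them stays open. With the replicate block, 2677 genes were higher, 2534 lower and 24 lists passed, and of the genes named here only Dnaja1, Marco and Prss34 lost their call.

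Uncalled genes changed sign as follows, and the cause was not tested. Tnfrsf13c was at -0.077 with library size only and -0.022 without a filter, and from -0.034 to 0.11 when 1 library was left out. Hbb-bs was at -1.05 with voom, -0.32 with each FPKM setting, -0.27 with the block, -1.22 without fibrosis 4 and 5 (adjusted p = 0.0262) and from -0.43 to 0.61 when 1 library was left out. Without fibrosis 4 and 5, Ighm was at 0.045, S100a8 at -0.13 and Tgfb1 at 0.036.

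Lists that changed direction had these adjusted p. Immediate-early: 0.976 with fry, 0.972 with library size only, 0.738 to 0.926 in the fits with 1 library left out that turned it (0.738 to 0.961 over all of these fits). Heat shock: 0.972 with library size only, 0.492 to 0.987 with 1 library left out, 0.995 with the GC offset and 0.632 with the erythroid covariate. Neutrophil: 0.845 with the block, 0.809 to 0.984 in the left-out fits that turned it (0.217 to 0.984 over all of these fits), 0.281 without fibrosis 4 and 5 and 0.588 with the erythroid covariate. Cholesterol biosynthesis and macrophage markers turned only without fibrosis 3, at 0.627 and 0.903. Over all fits with 1 library left out they were at 0.593 to 0.906 and 0.156 to 0.992. Without fibrosis 4 and 5, profibrotic factors were at 0.517, complement at 0.858 and mast cell markers at 0.915. With the erythroid covariate, interferon-gamma was at 0.260, plasma cells 0.860, oxidative phosphorylation 0.777 and erythroid markers 0.533. The immunoglobulin share differed by -0.034 to 0.14 and the haemoglobin share by -0.12 to 0.026 percentage points when 1 library was left out. Depth limits genes under 1 CPM most.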

Other observations

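Genes of stress responses and metabolism mostly did not move as groups. NRF2 and xenobiotic genes were higher in 3 and lower in 7 of 25 members, 3 and 7 adjusted over the list alone (adjusted p = 0.266 by camera, 0.0280 without fibrosis 4 and 0.00967 without fibrosis 4 and 5, over a range of 0.00967 to 0.763 across alternatives). Both subunits of glutamate-cysteine ligase, the enzyme that limits glutathione synthesis, fell, Gclc by 0.96 and Gclm by 1.13 on the log2 scale. The unfolded protein response was higher in 1 and lower in 3 of 25 members, 1 and 3 adjusted over the list alone (adjusted p = 0.462 by camera), and among these the asparagine synthetase gene Asns fell from 102 ± 13.5 to 26.6 ± 14.1 CPM and Atf4, its activator, by 0.33 on the log2 scale. Asns, and Pfkm below, were highest among the fibrosis libraries in fibrosis 4 and lowest in fibrosis 2 and 5, as the erythroid markers were, so whether these falls lie in B cells is not settled here. Nuclear-encoded oxidative phosphorylation genes fell in 7 of 39 members, 7 adjusted over the list alone (adjusted p = 0.389 by camera, and 0.00241 without fibrosis 4 and 5, over a range up to 0.945), among them the ATP synthase genes Atp5g1 at -0.83 ± 0.10 and Atp5b at -0.47 ± 0.09.

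Glycolysis genes were higher in 6 and lower in 3 of 21 members, 8 and 3 adjusted over the list alone (adjusted p = 0.362 by camera), with Pfkm at -1.95 ± 0.24 and Hk1 at -1.09 ± 0.14. Cholesterol biosynthesis genes were higher in 4 and lower in 1 of 23, 3 and 1 adjusted over the list alone (adjusted p = 0.798; 0.00649 to 0.958 over all alternatives), with Hmgcs1 at 0.68 ± 0.16. Immediate-early genes were higher in 4 and lower in 5 of 29, 4 and 8 adjusted over the list alone (adjusted p = 0.998), with Nr4a3 at 1.27 ± 0.19, Klf6 at 0.76 ± 0.11 and Egr1 at -0.71 ± 0.15. Heat shock genes were higher in 3 and lower in 1 of 16, 3 and 1 adjusted over the list alone (adjusted p = 0.998), with Dnaja1 at 0.79 ± 0.21, whose call ended with the replicate block (adjusted p = 0.0661) and with FPKM without a filter (0.0898), and Hspd1 at -0.48 ± 0.12. For immediate-early genes the median, -0.083, and for heat shock genes the mean, 0.13, differed in sign from the direction of the test. The sex-linked list had only 4 tested members, too few for the list test; 3 were higher, 3 adjusted over the list alone, with Ddx3y, a Y chromosome gene, at 0.78 ± 0.16.

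Genes of the exocrine pancreas and liver were looked at after Ctrb1 was seen. Of 16 pancreatic genes, 8 were tested, 7 of these were lower in fibrosis and Cela1, which is expressed more widely, was not called (-0.36 ± 0.41, adjusted p = 0.527 by edgeR). Among the lower ones, Pnlip had 4 counts over the fibrosis libraries against 302 over the controls, Cel 8 against 226, Prss2 27 against 166 and Cpb1 1 against 176. Controls held 20 to 146 counts of Pnlip each, with the highest in control 4. The other lower genes were also highest in control 4, with 291 counts of Ctrb1, 185 of Cela2a and 103 of Try4. These genes thus moved together across the controls, and whether their falls lie in B cells is not settled here. The summed counts of all 16 genes were 30.4 ± 20.2 CPM in fibrosis and 71.5 ± 35.3 CPM in control (exact permutation p = 0.0317), mostly from Cela1, with 2280 and 3545 counts. The albumin gene Alb went the other way, with 119 counts over the fibrosis libraries against 13 over the controls (3.33 ± 0.49).

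Of 21 circadian clock genes looked up after the values were seen, 18 were tested, 4 were higher, 1 was lower and 13 were not called. Nr1d2 rose by 1.51 ± 0.11, Clock by 0.65 ± 0.17, Per3 by 0.60 ± 0.16 and Tef by 0.41 ± 0.09, and Bhlhe41 fell by 0.39. Arntl, Per1, Per2, Cry1 and Dbp were among those not called. The time of day of tissue collection is not given in the sources used here.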
